A study of Mus musculus with 20 samples.

How the data were processed

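Droplet RNA libraries of sorted cells were analysed from the processed files alone. The first experiment held 8 RNA lanes: lanes 1, 3, 5 and 7 held blood and Organ 1, lanes 2, 4, 6 and 8 bone marrow and spleen, and each lane held 1 arm on 1 day (saline mice in lanes 1 to 4, mice with cyclophosphamide and AMD3100 at 5 mg/kg in lanes 5 to 8). The second held blood cells of 14 conditions in 2 lanes. The deposited matrices hold whole-number UMI counts per feature and barcode, which the authors made with Cell Ranger (version 3.1 and the mouse build mm10 per the labels, whereas the header of the second matrix gives version 6.0.2), without normalization. In the authors' filtered matrices barcodes were already called as cells. The deposited tables per cell give the authors' hashtag identity (mouse, organ, treatment, day) and doublet calls, without a tool, and no cell type names for the first experiment. Of those tables, 2 columns were not used.

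Of the 50936 barcodes of the first experiment the authors called 42433 singlets, 7183 doublets or multiplets and 1320 negatives. A further 42 within-hashtag doublets were left out, and 42391 cells were used. Of these, 6678 have fewer than 500 genes or at least 10% mitochondrial UMIs and were kept, with their removal as an alternative. Cells whose neighbours were most often known hashtag doublets were marked as doublet-like (1025 cells, 2.42%), in the number expected from the hashtag doublets of the lane, and removed as an alternative. In the second experiment 2374 of 3426 barcodes were used. Raw matrices served only to measure the free RNA of each lane in barcodes of at most 100 UMIs.

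Counts were scaled per cell, log-transformed and reduced to 30 principal components of 2000 variable genes, and cells were clustered by the Leiden method at resolution 1.0 (2.0 as an alternative) on graphs of 20 neighbours, without correction between lanes (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9). Each cluster was named from 15 marker sets fixed before the data were examined. The rule needed 3 raised markers, and a marker among the 10 top genes or 50% of the set raised, with 20 counts-per-million added before each fold. Clusters that failed it stayed unnamed, and those led by mitochondrial genes were set apart.

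The replicate was the mouse. Both organs of a lane came from the same mice per the labels' mouse numbers, so comparisons of spleen with marrow had the mouse as a block. Their interaction with treatment had none. Each mouse number occurred in 1 lane per organ pair and 1 day, and the expression data hold no genotype that could test the pairing. Mice with Treatment 1 were left out of the comparisons of treatment and organ. Shares of classes were compared by two-sided exact permutation tests of the difference in mean share over the 70 splits of 4 against 4 mice, where the smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over the classes of an organ.

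Gene expression was tested on the summed UMI counts of each mouse, for all cells and for each class, with sums of fewer than 20 cells left out (50 as an alternative). The fits used edgeR 4.0.16 (TMM factors, filterByExpr, glmQLFit and glmQLFTest, two-sided) in R 4.3.3 with the day as a term, and Benjamini-Hochberg adjustment over the genes of a comparison at 0.05. Of 83 comparisons fitted (21 of treatment, 10 of organs, 4 of their interaction, 44 of Treatment 1 and 4 of its interaction with treatment, the last added after seeing the data), 32 were described. The others were further classes, down to 20 cells per sum, and sums over all cells for organs and their interaction, and gave 10 to 785 genes for treatment, 6 to 3051 for organs, 529 to 2592 for the interaction and 0 to 64 for Treatment 1, and are not reported here. The 25 fixed gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry. The counts given "over the list alone" adjust p over the members of the list.

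The genes named were fixed by a rule before the data were examined: the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean log2 level of at least 5 and no overlap between the groups, up to 3 members of each list by p, and Cxcr4, Cxcr2, Csf3r, Elane, Mki67 and Cdkn1a. Predicted genes, immunoglobulin segments and sex-linked genes were not named from the top genes. The text gives a choice of these genes, and where it names others it says so or gives them as list members.

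Depth differed between lanes, from 1694 to 2980 UMIs in the median cell, and 74 to 1809 cells stood behind a sum over all cells. Mice of 1 group and day differed by more than counting error: over 32 pairs the chi-square per degree of freedom was 1.77 to 17.8. The fits were tested on simulated data with 200 genes changed. For all spleen cells the fit recovered 13.2%, 64.5% and 98.3% of genes changed 1.5, 2 and 4 times, with 4.5% false calls. In the interaction in mature neutrophils these were 4.8%, 30.0% and 74.3%. Camera called 6 of 6 risen and 0 of 120 unchanged lists, which does not test real correlation between genes.

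The alternatives chosen before the data were examined were DESeq2 1.42.0, RLE factors, no filter on low counts, 50 cells per sum, equal numbers of cells per mouse, no day term, the mouse block, each day alone, leaving out each mouse, doublet removal, a minimum fold of 1.5, the second clustering for shares, the filter on genes and mitochondria for shares, and log ratios of shares. Those chosen after seeing the data were the mice with Treatment 1 alone, all mice with Treatment 1 as a term (for shares, relabelled within its groups), the filter and the second clustering for gene expression, the mouse block in the organ interaction, and shares within the neutrophil lineage. Other splits of the mice into groups of the same sizes were refitted, at most 100 per comparison, except the split that coincides with the day. Alternatives for the second experiment that need several mice could not be fitted, since its labels name no mouse.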

Results

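The data describe granulocytes and their progenitors in female C57BL/6J mice that received saline (saline mice) or cyclophosphamide, an alkylating drug that kills dividing marrow cells, followed by daily AMD3100 (treated mice). AMD3100 is an antagonist of the chemokine receptor CXCR4 that releases cells from the marrow. Single cells from blood, femoral bone marrow, spleen and an organ that the labels call Organ 1 were sorted as lineage-negative Gr1-positive or Gr1-negative cKit-positive cells. They were tagged with hashtag antibodies and sequenced as droplet RNA libraries with unique molecular identifiers (UMIs). The first experiment held 16 mice: 8 saline and 8 treated, and within each arm 4 mice also received a treatment that the labels call Treatment 1. Of the 50936 barcodes in 8 lanes, 42391 cells assigned to 1 mouse and 1 organ were used. Each mouse and organ gave 74 to 1809 cells and 166257 to 8899677 UMIs over 31053 genes, with a median of 2333 UMIs per cell. Saline and treated mice never shared a lane, so treatment and lane cannot be told apart. Spleen and marrow, blood and Organ 1, and mice with and without Treatment 1 lay within the same lanes. The median depth of a lane ran from 1694 to 2980 UMIs per cell, and spleen cells held a median of 1461 UMIs in saline and 3392 in treated mice. Per the labels, the numbers of sorted cells were evened across conditions, so a share below is a share of the sorted cells and not of the organ.

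Cells were named by their resemblance to fixed marker sets, and the suffix "-like" is omitted throughout. The neutrophil lineage ran from stem and progenitor cells (HSPC) to granulocyte-committed proNeu cells, which make primary granule enzymes such as Elane and Mpo. It went on over dividing preNeu cells and immature neutrophils, which make secondary granule proteins such as Camp and Ltf, to mature neutrophils, which express the chemokine receptor Cxcr2. Monocytes, dendritic cells, basophils with mast cells, T and NK cells, erythroid cells and macrophages formed the other named classes. Folds are log2 values ± SE from edgeR quasi-likelihood fits on the summed counts of each mouse, with a day term and Benjamini-Hochberg adjusted p, and groups hold 4 mice unless stated. Levels are means over mice in counts-per-million (cpm).

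The first question was how the cell classes of the spleen differ between treated and saline mice, here without Treatment 1. Immature neutrophils made up 3.05% ± 1.45 (SD, n = 4) of the sorted spleen cells of saline mice and 44.7% ± 5.70 (n = 4) of those of treated mice, and dividing preNeu cells rose from 1.48% ± 1.46 to 16.0% ± 2.18. The earliest stages rose as well: proNeu cells from 0.12% to 2.67% and HSPC from 0.29% to 1.19%. Mature neutrophils fell from 54.0% ± 11.6 to 16.9% ± 5.04, monocytes from 13.8% to 7.33% and T and NK cells from 2.10% to 0.36%. Erythroid cells rose from 0% to 0.66%, and the unnamed cluster 9 (3.50% to 1.45%) and mitochondrial (7.86% to 3.49%) cells fell. Each of these 10 shares did not overlap between the groups of 4 mice, so each gave the smallest two-sided exact permutation p that 4 against 4 mice allow, 0.0286, with an adjusted p of 0.040. Dendritic cells did not pass the test, with 10.4% in saline and 4.04% in treated mice. Leaving out saline mouse 2 raised the adjusted p of the 7 shares named first to 0.0571. In the mice with Treatment 1 the immature share differed by 15.6 points (adjusted p = 0.08) and the monocyte share by 1.44 in the other direction (adjusted p = 0.57).

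**Figure D1:**
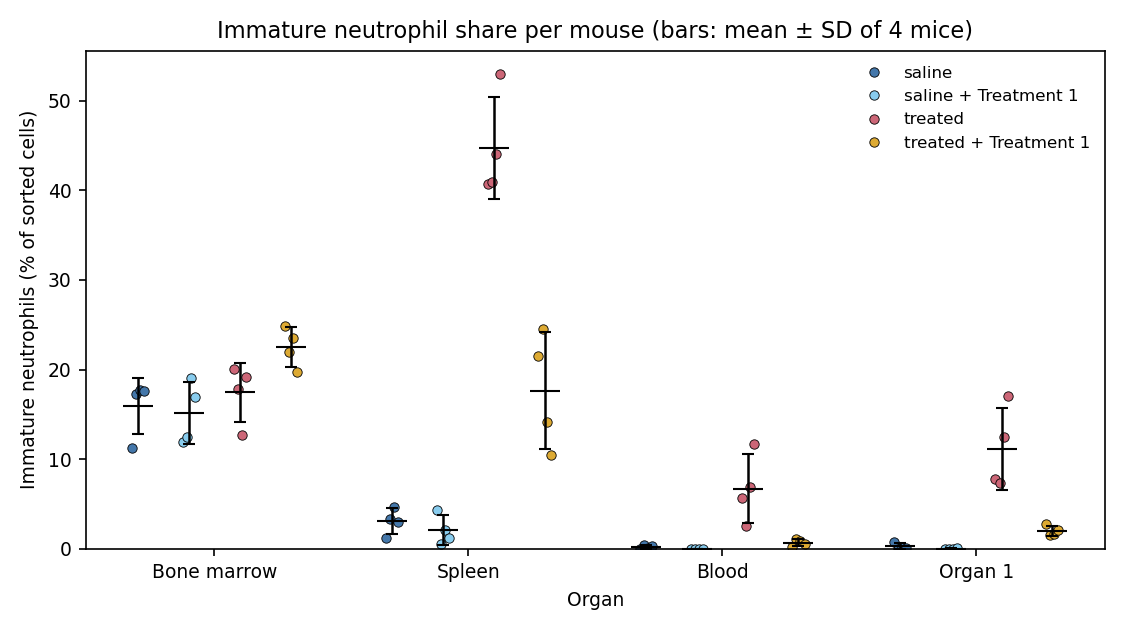
Share of immature neutrophils among the sorted cells (percent, linear axis from 0) for each mouse (points), with the mean ± SD of each group of 4 mice (bars), in 4 organs and 4 groups: saline, saline with Treatment 1, treated, and treated with Treatment 1. In the spleen the mean was 3.05% in saline, 44.7% in treated and 17.7% in treated mice with Treatment 1.

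In the bone marrow, blood and Organ 1 no share passed the adjusted test in the mice without Treatment 1. Mature neutrophils made up 36.6% ± 5.80 of the sorted marrow cells of saline and 50.8% ± 3.76 of those of treated mice (n = 4 each), and preNeu cells 15.6% ± 1.56 and 8.03% ± 1.35. These did not overlap either (two-sided exact permutation p = 0.0286), but both missed the threshold over the classes of the marrow (adjusted p = 0.186). Immature neutrophils were 15.9% and 17.5% and proNeu cells 7.56% and 3.67%, neither past the test. In the blood immature neutrophils were 0.20% ± 0.18 in saline and 6.71% ± 3.83 in treated mice, T and NK cells 3.21% and 0.55%, each with an exact p of 0.0286 and an adjusted p of 0.105. Mature neutrophils were close at 66.3% and 64.4%. In Organ 1 immature neutrophils were 0.29% ± 0.35 in saline and 11.2% ± 4.57 in treated mice (exact p = 0.0286, adjusted p = 0.200). Over all 16 mice, relabelled within the groups of Treatment 1, the shares of blood immature neutrophils (3.59 points, adjusted p = 0.0024) and T and NK cells (-2.26, adjusted p = 0.0086) and of marrow preNeu cells (-5.50, adjusted p = 0.027) passed. So did those of Organ 1 immature neutrophils (6.43, adjusted p = 0.0029) and preNeu cells (2.88, adjusted p = 0.0095) and of unnamed cells in blood and Organ 1, and the spleen monocyte share did not (-2.52, adjusted p = 0.18). The direction of the blood mature share turned without saline mouse 1 or treated mouse 9, and that of the marrow immature share without saline mouse 1.

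Over all spleen cells of a mouse, the genes of granule formation and of cell division rose together in treated mice. Camp, the cathelicidin of secondary granules, went from 3733 to 45200 cpm (log2 fold 3.68 ± 0.31, adjusted p = 3.5e-06) and Lcn2, a siderophore-binding protein of the same granules, rose by 2.95 ± 0.21. All 11 measured secondary granule genes rose, with Ltb4r1, a leukotriene receptor, at 2.02 ± 0.17. Of 9 primary granule genes 7 rose, among them the serine proteases Prtn3 (3.14 ± 0.32) and Elane (2.87 ± 0.38) and the peroxidase Mpo (1.88 ± 0.21). The other 2 fell. All 17 measured genes of the G2 and M phases rose, as did 16 of 17 S phase genes (17 when adjusted over the list alone), for example the cyclin-dependent kinase Cdk1 (2.40 ± 0.27), the proliferation marker Mki67 (1.97 ± 0.24) and the thymidylate synthase Tyms (2.08 ± 0.28). Ly6g, the surface antigen of the sorting antibody Gr1, rose by 3.29 ± 0.20, Cebpe, a transcription factor of granule gene expression, by 3.13 ± 0.27. Hist1h2ap rose by 4.54 ± 0.24, a value that is uncertain because histone genes have near-identical copies.

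Most immediate early and NF-kB genes fell in these spleens. The 11 measured immediate early genes had a median fold of -2.16 and 8 of them fell, led by the phosphatase Dusp1 (-3.92 ± 0.27) and the AP-1 subunits Fos (-2.98 ± 0.16) and Jun (-1.68 ± 0.16). Tissue dissociation is known to raise such genes. Of 12 NF-kB target genes 7 fell, among them the cytokine Il1b (-3.21 ± 0.26, from 702 to 73 cpm) and the adhesion molecule Icam1 (-2.31 ± 0.18). Of 11 genes of granulocyte colony-stimulating factor and STAT3 signalling 8 fell and 2 rose, with Junb at -2.62 ± 0.21 and the survival factor Mcl1 at -1.56 ± 0.21. The receptor genes Cxcr2 (-1.49 ± 0.34), a chemokine receptor of mature neutrophils, and Csf3r (-1.88 ± 0.31), the receptor of granulocyte colony-stimulating factor, fell, while Cxcr4 was not called (-0.27 ± 0.14, adjusted p = 0.15). Of 18 interferon response genes 11 fell, with Oasl2 at -1.82 ± 0.25, and of 15 p53 response genes 8 fell, with Btg2 at -1.20 ± 0.16. Cdkn1a, a p53-driven inhibitor of division, was at -0.68 ± 0.20 in the spleen (adjusted p = 0.014) and was not called over all cells of marrow (0.01 ± 0.21), blood (0.39 ± 0.32) or Organ 1 (-0.52 ± 0.28). Markers of other cells fell with them: all 7 MHC class II genes, for example Ciita (-1.72 ± 0.19), and all 7 measured monocyte and macrophage markers, for example Csf1r (-1.88 ± 0.22). Of 16 glycolysis genes 10 rose and 3 fell (4 over the list alone), with Gapdh at 1.58 ± 0.16. Of the oxidative phosphorylation genes 11 of 16 rose, with Cox5a at 1.40 ± 0.21, and 5 of 6 subunits of the NADPH oxidase rose, with Cyba at 1.47 ± 0.16. In total 4304 of 9664 genes changed, 2081 higher and 2223 lower, and 1914 passed a test against a fold of 1.5. The set test camera called these lists with a preset correlation. None held with an estimated correlation (adjusted p = 0.18 for secondary granule, immediate early and NF-kB genes, 0.23 for G2 and M genes, 0.19 for primary granule, glycolysis and p53 genes, and 0.20 to 0.51 for the others named here). Folds computed from the shares of classes alone had a slope of 0.706 against the measured folds of the 4304 genes, and genes are not independent replicates.

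Over all bone marrow cells, some genes of division fell and some of the interferon response rose. Of 17 G2 and M genes 5 fell (6 over the list alone), among them Nusap1, a spindle protein (-0.96 ± 0.12), the topoisomerase Top2a (-0.87 ± 0.15) and the cyclin Ccnb1 (-0.89 ± 0.17), and Mki67 fell by 0.56 ± 0.15. Mpo (-1.18 ± 0.27), Elane (-0.86 ± 0.26, adjusted p = 0.048), both of primary granules, and the ficolin Fcnb (-1.26 ± 0.14) of the secondary granule list fell, but Elane turned in the mice with Treatment 1 (0.24, not called). Retnlg, a resistin-like protein of mature neutrophils, rose from 4889 to 10340 cpm (1.06 ± 0.27) and the protease inhibitor Slpi by 0.97 ± 0.21, 2 of 10 gelatinase granule genes. Of 18 interferon response genes 10 rose (13 over the list alone), for example Rtp4 (1.59 ± 0.22), Ifi27l2a (1.63 ± 0.27) and the tetherin Bst2 (0.87 ± 0.14). MHC class II genes, which present antigen on dendritic cells and other cells, rose in 5 of 7 cases, with the invariant chain Cd74 going from 121 to 429 cpm (1.73 ± 0.26). Of 18 ribosomal protein genes 12 rose (14 over the list alone), with Rpl18 at 0.73 ± 0.12, of 16 oxidative phosphorylation genes 7 rose (9 over the list alone), with Atp5g1 at 0.67 ± 0.12, and of 9 heme and iron genes 5 rose, with the ferritin chain Fth1 at 1.29 ± 0.17. The p53 target Bax, which promotes apoptosis, rose by 0.82 ± 0.13, 1 of 2 risers in 13 p53 response genes. In total 1049 of 9152 genes changed, 631 higher and 418 lower. The estimated-correlation test kept no list (adjusted p = 0.78 for gelatinase granule genes and 0.32 for the other lists), and leaving out 1 mouse at a time gave 226 to 1163 genes. Folds from the shares of classes alone had a slope of 0.0818 against those measured.

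In the blood the largest folds were those of secondary granule genes. Camp rose from 90 to 6006 cpm (6.19 ± 0.78), Ngp, another cathelicidin-like granule protein, from 112 to 5473 (5.60 ± 0.72) and the lactoferrin Ltf from 39 to 1617 (5.18 ± 0.61), 3 of the 6 risers among 10 measured list members (9 over the list alone). Mki67 rose by 2.32 ± 0.33 from 4 to 24 cpm, Cebpe by 2.19 ± 0.33 and Ly6g by 2.42 ± 0.33. T and NK cell markers fell in 5 of 7 cases (6 over the list alone), with the T cell receptor subunit Cd3d at -1.32 ± 0.32. MHC class II genes rose in 4 of 7, with H2-Ab1 at 0.92 ± 0.18. Of 5 red cell genes 1 rose, the globin gene Hbb-bt (1.51 ± 0.35, a gene with near-identical copies). Dusp1 (-1.16 ± 0.21) and Fos (-0.86 ± 0.18) fell, 2 of 3 fallers among 10 immediate early genes, while Il1b was at -0.57 ± 0.15 (adjusted p = 0.059). In total 186 genes changed, 93 in each direction. No list held with an estimated correlation (adjusted p = 0.17 for secondary granule and T cell genes and 0.23 to 0.25 for MHC class II, red cell and immediate early genes). Day 1 alone gave 388 genes and day 2 alone 25, mice with Treatment 1 gave 19 with none higher and Ly6g and Cebpe turned (-0.41 and -0.22, not called), and leaving out 1 mouse gave 64 to 291.

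In Organ 1 genes of the G2 and M phases and many secondary granule genes rose. All 17 G2 and M genes rose, from levels near 0 in saline mice: Cenpf, a kinetochore protein, went from 3 to 69 cpm (5.02 ± 0.35) and Mki67 from 7 to 184 (4.03 ± 0.48). Of the treated mice, those of day 1 held 6.24% and 10.3% preNeu, 14.7% and 16.2% T and NK and 18.3% and 9.93% dendritic cells. Those of day 2 held 0% and 0.91%, 1.89% and 1.22%, and 0.47% and 2.44%. In the S phase list 3 of 13 rose (11 over the list alone), with the dUTPase Dut at 2.19 ± 0.45. Of 11 secondary granule genes 7 rose, with Camp at 5.28 ± 0.87, Lcn2 at 3.06 ± 0.30 and Fcnb at 4.59 ± 0.47. Of 6 primary granule genes 3 rose, with Prtn3 at 3.39 ± 0.82 (adjusted p = 0.045). Of 12 immediate early genes 8 fell (10 over the list alone), with Fos at -2.20 ± 0.17 and Zfp36, an mRNA decay factor, at -1.69 ± 0.24. In the NF-kB list 6 of 15 genes fell (8 over the list alone), with the cyclooxygenase Ptgs2 at -3.62 ± 0.38 and Il1b at -1.86 ± 0.34. Cxcr4 fell by 0.80 ± 0.20 (adjusted p = 0.048), in sorted cells of changed composition. In total 339 genes changed, 227 higher and 112 lower. The G2 and M, immediate early and NF-kB lists held with an estimated correlation (adjusted p = 0.034, 0.034 and 0.039). Secondary and primary granule genes did not (adjusted p = 0.09 and 0.21) and S phase genes did not either (adjusted p = 0.21). Day 1 alone gave 2014 genes and DESeq2 562, and leaving out 1 mouse gave 138 to 481.

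In preNeu and proNeu cells of the bone marrow, ribosomal protein genes rose. In preNeu cells 13 of 18 ribosomal protein genes rose, with Rpl13 at 0.73 ± 0.13. Oxidative phosphorylation genes rose in 6 of 16 cases (7 over the list alone), with Atp5g1, an ATP synthase subunit, at 0.95 ± 0.18. Mmp8, a collagenase of neutrophil granules, fell from 115 to 10 cpm (-3.37 ± 0.51), and Foxm1, a transcription factor of mitosis, fell by 1.37 ± 0.27. Mki67 (-0.33 ± 0.14, adjusted p = 0.12) and Elane (adjusted p = 0.99) were not called. In total 485 genes changed in preNeu cells. A minimum of 50 cells kept 3 saline mice and 1 treated mouse and gave 35 genes, if that mouse varies like the others. In proNeu cells (4 saline and 2 treated mice) 15 of 18 ribosomal protein genes rose, with Rps4x at 0.85 ± 0.12, and Cenpa, a centromeric histone, rose by 1.38 ± 0.21, 1 of 2 risers among 16 G2 and M genes (3 over the list alone). Vcam1, an adhesion molecule that holds progenitors in the marrow, fell by 1.61 ± 0.49, 1 of 5 genes of the CXCR4 axis, and Fcnb by 1.49 ± 0.19. Vcam1 turned in the mice with Treatment 1 (0.87, called) and with all mice (0.35, not called). Elane (-0.27 ± 0.14) and Cxcr4 (-0.62 ± 0.26) were not called (adjusted p = 0.23 and 0.14). Of 542 changed genes in proNeu cells 46 were left in cells with at least 500 genes and under 10% mitochondrial UMIs. None of these lists held with an estimated correlation (adjusted p = 0.58 for both preNeu lists and 0.40 for the proNeu lists named).

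In immature neutrophils of the marrow some gelatinase granule genes rose: Retnlg from 4261 to 9885 cpm (1.26 ± 0.16), Slpi by 0.76 ± 0.15 and Pglyrp1, a peptidoglycan-binding protein, by 0.55 ± 0.13, 3 of 9 (5 over the list alone). The ferritin chains Fth1 (1.05 ± 0.15) and Ftl1 (1.02 ± 0.12), which store iron, rose as 2 of 4 heme and iron genes. The interferon-induced genes Ifitm3 (0.74 ± 0.13) and Ifi27l2a (1.23 ± 0.22) rose as 2 of 3. Etv6, a transcription factor of blood progenitors, fell by 1.73 ± 0.39. In mature neutrophils of the marrow secondary granule genes fell in 6 of 10 cases (8 over the list alone) and rose in 1: Ltf fell from 3154 to 1059 cpm (-1.55 ± 0.18), Ngp by 0.84 ± 0.13 and Chil3, a chitinase-like lectin, by 0.98 ± 0.15. With the second clustering Ltf and Ngp turned, to 0.40 and 0.19, and were not called. Ifi27l2a rose by 1.79 ± 0.19 and Rtp4 by 1.29 ± 0.19, 2 of 4 risers among 12 interferon response genes (9 over the list alone), and Fth1 and Ftl1 rose by 1.21 ± 0.13 and 1.24 ± 0.13. The receptors Fpr2 (-0.80 ± 0.12), which binds formyl peptides, and Itgam (-0.59 ± 0.11), an integrin chain, were 2 of 4 fallers among 15 receptor and adhesion genes. Cxcr2 and Cxcr4 were not called (-0.09 ± 0.12 and -0.08 ± 0.15). Elane (-1.87 ± 0.43), Mpo (-1.54 ± 0.31) and Cd74 (-1.73 ± 0.32) fell too, at 10 to 58 cpm. Free RNA in the droplets held Elane and Mpo at 718 and 1305 cpm in the saline marrow and spleen lane of day 1 and at 541 and 347 in that of treated mice, and on day 2 at 660 and 1054 and at 312 and 387. The saline mature class was 19.5% cluster 1, 14.2% cluster 4 and 62.2% cluster 5, and the treated one 5.5%, 34.0% and 53.8%. In total 240 genes changed in immature and 414 in mature neutrophils. With an estimated correlation no list held (adjusted p = 0.15 to 0.39 and 0.17 to 0.34), and day 2 alone gave 80 and 183 genes.

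Immature neutrophils of the spleen differed in 146 genes between 3 saline and 4 treated mice. Slpi rose by 1.01 ± 0.14, Pglyrp1 by 0.57 ± 0.09 and Retnlg by 0.39 ± 0.10, 3 of 10 gelatinase granule genes (5 over the list alone). Cyba, the membrane subunit of the NADPH oxidase, rose by 0.71 ± 0.11 as 1 of 3 risers among its 6 subunits. Ftl1 and Fth1 rose by 0.81 ± 0.12 and 0.78 ± 0.13. Btg1, an inhibitor of division (-1.38 ± 0.18), the hexokinase Hk2 (-1.27 ± 0.21) and the chemokine receptor Ccr1 (-1.24 ± 0.21) fell, and Cxcr4 and Cxcr2 were not called (adjusted p = 1.0 and 0.77). The lists named did not hold with an estimated correlation (adjusted p = 0.096 to 0.11). Sums of at least 50 cells kept 1 saline mouse and gave 44 genes, if that mouse varies like the treated ones.

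Many granule genes rose on average in spleen mature neutrophils of treated mice. Retnlg rose from 6433 to 31750 cpm (2.30 ± 0.16), Camp from 1371 to 6019 (2.22 ± 0.22) and Cd177, a surface glycoprotein of neutrophils, from 145 to 669 (2.21 ± 0.20). Of 10 secondary granule genes 8 rose (9 over the list alone), with the lysozyme Lyz2 at 1.87 ± 0.16. Of 10 gelatinase granule genes 6 rose, with Mmp9, a gelatinase, at 0.84 ± 0.15. Cybb, the catalytic subunit of the NADPH oxidase, rose by 1.91 ± 0.22 as 1 of 4 risers among 6 subunits (5 over the list alone), and Ifitm3 by 1.01 ± 0.16 as 1 of 5 among 13 interferon response genes. Il1b (-1.10 ± 0.16), the lipopolysaccharide co-receptor Cd14 (-2.63 ± 0.49), Dusp1 (-1.90 ± 0.21), Fos (-1.36 ± 0.19) and Junb (-1.19 ± 0.16) fell. In the mice with Treatment 1 Il1b was at 0.020 and not called. In their lists 4 of 8 NF-kB, 3 of 8 immediate early (4 over the list alone) and 4 of 11 colony-stimulating factor genes were lower (5 over the list alone). Csf3r (-0.55 ± 0.15) and Cxcr2 (-0.41 ± 0.14, adjusted p = 0.041) fell and Cxcr4 was at -0.50 ± 0.22 (adjusted p = 0.12). Elane (-3.52 ± 0.65, from 65 to 5 cpm) and Mpo (-2.82 ± 0.43) fell. T, NK, dendritic and cluster 9 cells of the saline spleens held 1.61 times as many UMIs of these genes per cell as mature neutrophils did. Cluster 1 was 61.7% of the saline and 19.2% of the treated mature class, and cluster 5 was 2.48% and 29.9%. In total 563 genes changed. No list held with an estimated correlation (adjusted p = 0.11 for secondary and 0.14 for gelatinase granule genes and 0.17 to 0.34 for the others).

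In spleen monocytes genes of cell division rose: all 14 S phase genes and all 14 G2 and M genes measured. The replicative helicase subunit Mcm6 rose by 3.41 ± 0.36 (from 13 to 156 cpm), the cyclin Ccnb2 by 3.48 ± 0.48 and Mki67 by 2.16 ± 0.42. Prtn3 (2.95 ± 0.35) and Elane (2.92 ± 0.45) rose, 2 of 3 risers among 6 primary granule genes. The class pools 4 clusters: cluster 12, marked by the replication genes Hist1h1b and Pclaf, was 2.58% of the saline and 39.7% of the treated class and cluster 7 was 47.4% and 15.0% (adjusted p = 0.0571 for both), so changes within a cluster are not separated from this shift. MHC class II genes fell in 5 of 7 cases, with H2-Aa at -2.15 ± 0.24 (0.076 in the mice with Treatment 1, not called) and its transactivator Ciita at -3.32 ± 0.70. Ace, an enzyme of patrolling monocytes, fell by 2.45 ± 0.40. Of 18 ribosomal protein genes 15 rose, with Rpl32 at 0.78 ± 0.10, and of 16 oxidative phosphorylation genes 13 rose (14 over the list alone). In total 1578 genes changed, and day 2 alone gave 257. With an estimated correlation no list held (adjusted p = 0.16 for S phase, 0.18 for MHC class II and 0.28 for the other lists named).

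In blood mature neutrophils Camp rose from 12 to 855 cpm (5.80 ± 0.26, adjusted p = 5.2e-16), Ltf from 7 to 306 (4.86 ± 0.32) and Ngp from 56 to 1205 (4.43 ± 0.27). These and Cd177 (1.10 ± 0.21) were the 4 risers among 10 secondary granule genes (4 over the list alone), a list that held with an estimated correlation (adjusted p = 0.011). In the mice with Treatment 1 Camp (-0.29), Ltf (-1.13), Ngp (-0.18), Cd177 (-0.006), Wfdc17 (0.23) and Il1b (0.27) turned and were not called. The 10% of mature blood cells with the most UMIs of Camp, Ltf and Ngp held 98.0% of them. Free RNA in the blood and Organ 1 lanes held Camp at 1057 and 1898 cpm in saline and at 6586 and 3064 in treated mice. Ptgs2 fell by 1.66 ± 0.27, Dusp1 by 1.06 ± 0.17, Il1b by 0.49 ± 0.14 (adjusted p = 0.049) and Wfdc17, a secreted inhibitor of inflammation, by 1.34 ± 0.19. In their lists 3 of 9 NF-kB and 3 of 10 immediate early genes fell, and the NF-kB list had a median of 0.01 although camera gave the direction down. Cxcr4 was not called (-0.44 ± 0.16, adjusted p = 0.13) nor was Cxcr2 (-0.13 ± 0.13). In Organ 1 mature neutrophils Camp (4.15 ± 0.60), Ngp (3.82 ± 0.56) and Ltf (3.45 ± 0.56) rose, 3 of 4 risers among 10 list members (7 over the list alone), as did Cybb (1.64 ± 0.26). The early response factor Egr1 fell from 312 to 11 cpm (-4.69 ± 0.34), Ptgs2 by 3.39 ± 0.40 and Cxcl2, a neutrophil-attracting chemokine, by 3.78 ± 0.60, with 6 of 9 immediate early genes (8 over the list alone) and 4 of 9 NF-kB genes lower (5 over the list alone). In total 106 genes changed in blood and 83 in Organ 1. No other list held with an estimated correlation (adjusted p = 0.33 for NF-kB and immediate early genes in blood and 0.13 for secondary granule, NF-kB and immediate early genes in Organ 1). Cluster 1 was 77.7% of the saline and 55.7% of the treated mature class in blood and 83.2% and 52.3% in Organ 1. Day 2 alone gave 27 genes in blood, and day 1 alone gave 14 in Organ 1.

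**Figure D2:**
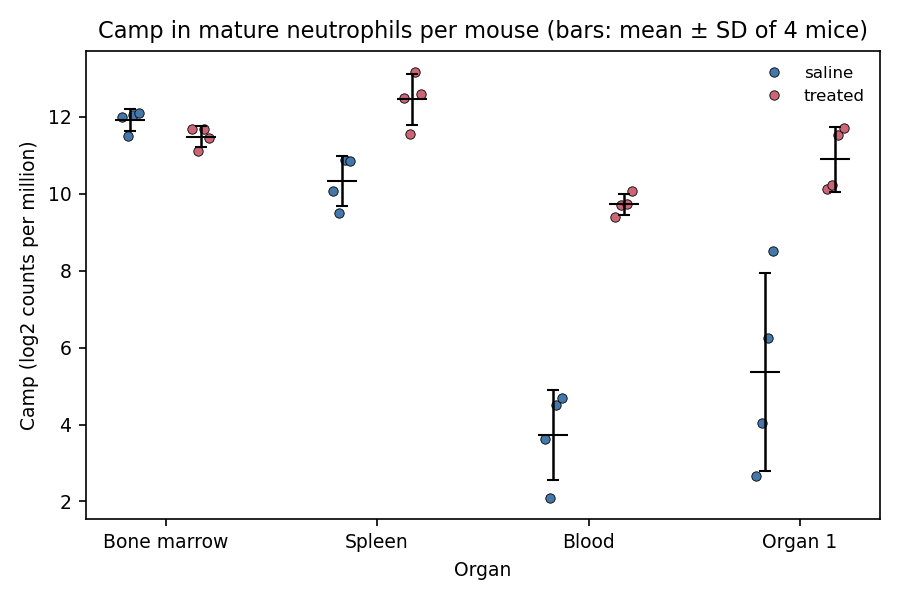
Camp expression in mature neutrophils (log2 cpm, y axis) for each mouse without Treatment 1 (points) with the mean ± SD of 4 mice per group (bars) in bone marrow, spleen, blood and Organ 1. In spleen, blood and Organ 1 the treated mice were higher, with log2 folds of 2.22, 5.80 and 4.15.

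Some genes moved alike in 6 to 13 treatment comparisons and thus with lanes. The transcript AC160336.1 fell in all 13 comparisons described above, with folds from -2.86 to -1.71, the amino acid transporter Slc38a2 in all 13 (-1.67 to -0.95), and the ribosomal gene Rps28, which has near-identical copies, in all 13 (-1.49 to -0.57). The mitochondrial gene mt-Atp8 fell in 9 (-2.47 to -1.17) and Polr2l, an RNA polymerase subunit, in 6 (-2.80 to -1.43). The ubiquitin gene Ubb, whose repeats make its value uncertain, rose in 10 (0.51 to 1.51), Fth1 in 8 (0.59 to 1.29), Ftl1 in 8 (0.69 to 1.24) and Ifi27l2a in 9 (0.65 to 1.79), while Fos fell in 9 (-2.99 to -0.80), Dusp1 in 8 (-3.92 to -1.06) and Junb in 7 (-2.62 to -0.57). These genes were chosen after seeing the values.

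The next question was how neutrophils of the spleen differ from those of the marrow of the same mice, within lanes and with the mouse as a block. In saline mice mature neutrophils of the spleen held fewer granule transcripts: Mmp8 went from 6909 cpm in marrow to 1093 in spleen (-2.69 ± 0.08), Retnlg from 33950 to 6013 (-2.48 ± 0.08), Lcn2 fell by 2.02 ± 0.07 and Cd177 by 2.68 ± 0.12. All 10 secondary and 8 of 10 gelatinase granule genes were lower, as were 5 of 6 NADPH oxidase subunits, with Cybb at -2.23 ± 0.09. So were 11 of 15 glycolysis genes, with 1 higher. Il1b rose from 557 to 2869 cpm (2.42 ± 0.08) and Csf1, the growth factor of macrophages, by 3.01 ± 0.17, in a list with 8 of 11 NF-kB genes higher (1 lower over the list alone). Of 10 immediate early genes 8 were higher, with Dusp1 at 1.65 ± 0.07. All 3 measured genes of the CXCR4 axis were higher in the spleen, the integrin chains Itga4 (2.24 ± 0.11) and Itgb1 (1.17 ± 0.28) and Cxcr4 itself (0.99 ± 0.09), as was Csf3r (1.11 ± 0.07). Cxcr2 was not called (0.16 ± 0.07, adjusted p = 0.062). In total 1729 genes differed, 850 higher and 879 lower, and DESeq2 called 952. Secondary granule genes held with an estimated correlation (adjusted p = 0.026). Gelatinase granule (adjusted p = 0.074), CXCR4 axis and NADPH oxidase (adjusted p = 0.17), NF-kB (0.24), immediate early (0.29) and glycolysis genes (0.30) did not. Cluster 1 made up 61.7% of the mature class in the spleen and 19.5% in the marrow.

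In treated mice 3 classes were compared between the organs in the same way. In immature neutrophils the spleen had less Retnlg (-1.18 ± 0.05, from 8881 to 3897 cpm), Mmp8 (-0.70 ± 0.05) and S100a6, a calcium-binding protein (-0.71 ± 0.05), and more Chil3 (0.56 ± 0.05), Camp (0.38 ± 0.04) and Orm1, an acute phase protein (0.98 ± 0.13). Of 11 secondary granule genes 6 were higher and 1 lower (8 and 1 over the list alone). The formyl peptide receptor Fpr1 (-0.72 ± 0.18) and Cxcr2 (-0.36 ± 0.10, adjusted p = 0.049) were 2 of 3 lower receptor genes among 14, and Cxcr4 was not called (-0.15 ± 0.14). In preNeu cells Camp (0.25 ± 0.05), the chitinase-like Chil1 (0.62 ± 0.12) and Ifitm3 (0.52 ± 0.09) were higher and Fcnb lower (-0.30 ± 0.08), with 2 secondary granule genes higher and 1 lower among 10 (4 and 1 over the list alone). With the second clustering edgeR called no preNeu gene (846 at an unadjusted p under 0.05), Ifitm3 turned to -0.14 and Fcnb to 0.36. Fcnb also turned in the mice with Treatment 1 (0.079, not called), and leaving out 1 mouse gave 1 to 20 genes. In mature neutrophils Csf1 (2.29 ± 0.28), Itga4 (1.45 ± 0.19), Il1b (1.32 ± 0.12) and Csf3r (0.46 ± 0.10) were higher in the spleen and Retnlg lower (-0.78 ± 0.09). Clusters 1 and 5 were 19.2% and 29.9% of the class in the spleen and 5.5% and 53.8% in the marrow. Ltf (0.75 ± 0.10) and Camp (0.69 ± 0.10) were higher too, 2 of 4 such secondary granule genes among 10, with 1 lower. Both turned in the mice with Treatment 1 (Ltf -0.51 and Camp -0.99, both called) and with the second clustering (-0.17 and -0.0014, not called). Of 6 NF-kB genes 2 were higher, and 3 of 6 immediate early genes (4 over the list alone). In total 20 genes differed in preNeu cells, 79 in immature and 105 in mature neutrophils, and DESeq2 called 4, 18 and 29. No list held with an estimated correlation (adjusted p = 0.22 in preNeu, 0.13 to 0.46 in immature and 0.14 to 0.34 in mature neutrophils). Without the mouse block preNeu and mature cells gave 11 and 64.

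Whether the treatment effect differed between spleen and marrow was tested as the interaction of organ and treatment. In mature neutrophils the effect on secondary granule genes was more positive in the spleen than in the marrow, where Ltf and Ngp fell, by 2.81 ± 0.31 for Ltf, 2.80 ± 0.26 for Ngp, 2.49 ± 0.23 for Mmp8 and 2.78 ± 0.26 for Cd177, with 9 of 10 genes called (10 over the list alone). This list held with an estimated correlation (adjusted p = 0.0005). Retnlg differed by 1.67 ± 0.21, 1 of 5 such genes among 10 of the gelatinase granules, and Cybb by 2.21 ± 0.25. Il1b (-1.10 ± 0.20), Cd14 (-2.75 ± 0.87), Junb (-0.87 ± 0.19) and Csf3r (-0.70 ± 0.17) differed the other way (adjusted p = 0.16 with an estimated correlation for gelatinase granule, NADPH oxidase, NF-kB and colony-stimulating factor genes). Cxcr4 (-0.40 ± 0.28) and Cxcr2 (-0.33 ± 0.18) were not called. Cluster 5 went from 2.48% to 29.9% of the mature class in the spleen and from 62.2% to 53.8% in the marrow, a shift not separated from changes within cells. In total 253 genes differed without a mouse block, 401 with it and 30 with the finer clustering. With the block the 10 folds called above stayed called, and no list was retested. In immature neutrophils edgeR and DESeq2 called no gene, 149 had an unadjusted p under 0.05 and 1 passed with the block.

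Treatment 1 shared lanes with its controls, and its shares of cell classes were compared after seeing the data. In the spleen of treated mice immature neutrophils made up 44.7% ± 5.70 without and 17.7% ± 6.50 with Treatment 1 (n = 4 each). Mature neutrophils were 16.9% and 30.5%, monocytes 7.33% and 16.4%, and erythroid cells 0.66% and 3.24%, each without overlap (two-sided exact permutation p = 0.0286, adjusted p = 0.10). In the marrow mature neutrophils were 50.8% and 38.2% and preNeu cells 8.03% and 14.4% (exact p = 0.0286, adjusted p = 0.186). In the blood immature neutrophils were 6.71% and 0.68% (adjusted p = 0.314), and in Organ 1 immature neutrophils 11.2% and 2.00% and monocytes 16.5% and 36.8% (exact p = 0.0286, adjusted p = 0.200). The effect on spleen immature neutrophils differed from that in saline mice by -26.0 points (two-sided permutation p = 0.023 over 4900 relabellings, adjusted p = 0.133).

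Over all spleen cells of treated mice, Treatment 1 lowered granule genes and raised red cell and ribosomal genes. All 11 secondary granule genes fell, with Lcn2 going from 14500 to 5331 cpm (-1.59 ± 0.18), Ltf at -1.56 ± 0.17 and Mmp8 at -1.51 ± 0.11. So did 9 of 10 gelatinase granule genes, with Mmp9 at -1.43 ± 0.13, and all 6 NADPH oxidase subunits, with Ncf1 at -1.21 ± 0.12. Of 16 glycolysis genes 13 fell, with Hk3 at -1.30 ± 0.14. All 7 measured red cell genes rose, among them the carbonic anhydrase Car2 (2.14 ± 0.21) and Klf1, a transcription factor of red cells (2.13 ± 0.24), together with the erythroid share given above. All 18 ribosomal protein genes rose, with Rplp1 at 0.83 ± 0.11. In the S phase list 12 of 17 genes rose, with the replication factor Cdc6 at 1.08 ± 0.14, while 7 of 17 G2 and M genes fell, with Nusap1 at -0.67 ± 0.11. Of 7 monocyte and macrophage markers 6 rose, with the chemokine receptor Ccr2 at 0.60 ± 0.11. Cxcr4 fell from 122 to 73 cpm (-0.74 ± 0.11), and Thbs1, the matrix protein thrombospondin, by 2.69 ± 0.27. In total 3673 genes changed, 609 of them against a fold of 1.5. With an estimated correlation no list held (adjusted p = 0.25 for secondary and 0.18 for gelatinase granule genes, 0.14 for red cell genes and 0.29 to 0.44 for the others). Folds from the shares of classes alone had a slope of 0.737 against those measured.

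Granule genes also fell under Treatment 1 in blood and Organ 1 of treated mice. In the blood Camp fell from 6156 to 424 cpm (-3.73 ± 0.43), Ltf by 3.76 ± 0.45 and Ly6g by 3.15 ± 0.35, with 7 of 10 secondary granule genes lower (8 lower and 2 higher over the list alone). Also lower were 9 of 10 gelatinase granule genes and 11 of 15 receptor and adhesion genes (13 over the list alone), among them the complement receptor C5ar1 (-0.99 ± 0.18) and Cxcr2 (-0.73 ± 0.17). All 18 ribosomal protein genes rose, with Rps18 at 0.53 ± 0.08. The proteoglycan gene Vcan (1.53 ± 0.20) and F13a1, a coagulation factor chain (0.82 ± 0.12), rose too. In Organ 1 Ltf (-2.39 ± 0.23), Lcn2 (-2.27 ± 0.23) and Cebpe (-1.71 ± 0.25) fell, with 7 of 11 secondary (9 over the list alone) and 5 of 10 gelatinase granule genes lower (7 over the list alone). Ccr2 rose by 0.77 ± 0.13, 1 of 5 risers among 10 monocyte and macrophage markers. In the marrow Elane rose from 578 to 1359 cpm (1.22 ± 0.23) and Ube2c, a ubiquitin carrier of mitosis, by 0.68 ± 0.13, while Cxcr2 (-0.52 ± 0.10) and the MHC class II gene H2-Aa (-1.29 ± 0.25) fell. There 2 of 17 G2 and M genes rose (16 over the list alone), 2 of 9 primary granule genes (7 over the list alone, with 1 lower) and 3 of 7 MHC class II genes fell (5 over the list alone). In total 879 genes changed in blood, 340 in Organ 1 and 55 in marrow, and without the day term 406, 10 and none. Leaving out 1 mouse gave 403 to 1158, 95 to 746 and 12 to 212 genes. Folds from the shares of classes alone had slopes of 0.639 in blood and 0.642 in Organ 1. None of these lists held with an estimated correlation (adjusted p = 0.19 to 0.27 for blood granule, receptor and ribosomal genes, 0.23 for Organ 1 granule and monocyte genes, and 0.31 to 0.38 in the marrow).

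Within mature neutrophils of the treated spleens Treatment 1 lowered Camp from 6119 to 2215 cpm (-1.49 ± 0.21), Ngp by 1.37 ± 0.17 and Mmp8 by 1.22 ± 0.15, 3 of 8 fallers among 10 secondary granule genes (9 over the list alone), and raised Wfdc17 (1.59 ± 0.17), Il1b (0.70 ± 0.13) and Junb (0.71 ± 0.14). Cluster 5 was 29.9% of the mature class without and 12.1% with Treatment 1, and cluster 1 was 19.2% and 27.7%. In total 71 genes changed, and secondary granule genes missed the threshold with an estimated correlation (adjusted p = 0.10). A regrouping of the same mice gave up to 36 genes.

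In saline mice Treatment 1 changed 1 gene in the marrow, Thbs1 (-0.77 ± 0.11), and 3 in the spleen, among them the antibody light chain gene Igkc (-6.13 ± 0.87), a marker of B cells. In Organ 1 15 genes fell, among them the phosphatase Dusp16 (-1.67 ± 0.18) and the monocyte genes Ace (-0.89 ± 0.17) and Treml4 (-1.16 ± 0.21). In the blood edgeR called no gene, DESeq2 called 1, and 289 genes had an unadjusted p under 0.05. Camera with a preset correlation called 30 lists in these 4 comparisons and none with an estimated correlation, so these lists rest on the preset value.

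The test of whether the Treatment 1 effect differed between treated and saline mice was added after seeing the data. In the spleen 89 genes differed, 29 more positive and 60 more negative in treated mice, among them the heme synthesis gene Cpox (1.66 ± 0.26), the biliverdin reductase Blvrb (1.66 ± 0.35), Hk3 (-1.27 ± 0.23), Rac2 (-0.94 ± 0.18), a GTPase of the NADPH oxidase, and Padi4 (-1.29 ± 0.30), which citrullinates histones. In the blood 15 genes differed, among them Ly6g (-2.84 ± 0.54), Mmp8 (-1.79 ± 0.37) and Serpinb1a, an inhibitor of neutrophil proteases (-2.52 ± 0.49). In marrow and Organ 1 edgeR called no gene, DESeq2 called 0 and 14, and 439 and 589 genes had an unadjusted p under 0.05. No list held with an estimated correlation. The count in the spleen was 323 with DESeq2 and 0 with equal numbers of cells per mouse, and regrouping the same mice gave up to 1666 genes in the spleen and 1112 in the blood.

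Across the 32 comparisons described, camera with a preset correlation called 267 of 636 lists, fry called 136 and camera with an estimated correlation called the 6 named above. Some lists were called rarely. Cholesterol synthesis genes were called once up and once down, granulocyte transcription factors once in each direction, CXCR4 axis genes once up and once down, and B cell markers once down among 8 comparisons in which they could be tested. Receptor and adhesion genes of neutrophils were called down in 18 comparisons and never up, and ribosomal protein genes up in 19 and down in 2. The median and the mean of a list had opposite signs in 59 of the 636 tests. Platelet markers could not be tested in any of them.

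The second experiment held blood cells of 14 conditions, each in 1 lane and without mouse labels, so it has no replicates. Intervals are exact 95% Clopper-Pearson intervals. Limits for a count of 0 are 3 counts of the total, with the upper end of the exact interval in brackets, and both cover counting error only. Of 3426 barcodes 2374 cells were used, with a median of 1584 UMIs. The labels do not say which conditions received saline and which cyclophosphamide with AMD3100. Immature neutrophils were 71 of 896 cells (7.92%, 6.24 to 9.89) in the IgG antibody condition and 43 of 772 cells (5.57%, 4.06 to 7.43) in the sham operated condition sorted without enrichment. After enrichment in the myeloid gate they were 2 of 123 cells (1.63%, 0.20 to 5.75) in sham operated and 0 of 104 cells, which allows a share of up to 2.88% (3.48%), in splenectomised mice, so a difference was not detectable at this depth. They were 7 of 100 (7.00%) with IgG, 6 of 92 (6.52%) with the CXCR2 condition and 6 of 99 (6.06%) with partial irradiation. In the stem cell gate 13 of 29 cells (44.8%, 26.4 to 64.3) were immature neutrophils with partial irradiation, 4 of 26 (15.4%) in sham operated and 0 of 18, which allows up to 16.7% (18.5%), in splenectomised mice. Mature neutrophils of the IgG and sham conditions without enrichment held Cxcr4 at 622 (533 to 722) and 1057 (926 to 1200) cpm and Cxcr2 at 3331 and 3415, with exact Poisson intervals, and Camp at 32.5 and 44.6, against 21136 and 22983 in their immature neutrophils.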

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

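The tests of shares of classes, free RNA, doublets and lanes below were chosen after the results were seen, as were the tests of Treatment 1 on shares and of its difference between arms; the splits of the mice were planned.

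The spleens of treated mice held fewer immature neutrophils with Treatment 1, and this effect minus that in saline mice was -26.0 points (two-sided permutation p = 0.023, adjusted p = 0.133). Lanes are argued against by design, as 0 held only mice with or only mice without Treatment 1. Loss of shallow cells is argued against too. Among cells with at least 500 genes and under 10% mitochondrial UMIs the share was still 0.476 times that without Treatment 1. Other technical sources were not tested. Whether the falls of Lcn2 and Ltf over all cells reflect shares alone cannot be told. Folds from shares alone, with a slope of 0.737 against those measured, leave room for both. A biological effect of Treatment 1 stays open and was tested only by the fits above.

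In Organ 1 of treated mice on day 1, T cells made up 11.7% to 16.2% and dendritic cells 8.30% to 18.3% of the cells (1.44% to 4.43% in blood), and progenitors were present. Blood cells of the same lane with a wrong hashtag are argued against, since the T and NK share in the blood was 0.0596 times that in Organ 1. Spleen or marrow cells are argued against for the T cells, as the main T cell cluster (350 of its 352 cells in Organ 1) held 0% of the spleen or marrow cells of those mice. For the progenitors the median ratio of preNeu with proNeu to immature cells was 1.42 in Organ 1 and at most 0.76 in spleen and marrow, although mouse 9, at 0.63, lay within the range of the other organs. Doublets cannot be told apart, with a doublet-like share 1.18 times that of other cells (4.06% of 566 against 3.43% of 1980 cells), and blood left in the organ or a day effect may add to the pattern and was not tested.

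Mean Camp, Ltf and Ngp rose in blood and spleen mature neutrophils of treated mice. In blood, free RNA is argued against for the mean rise only: monocytes gained 0.0772 times as many UMIs per cell as mature neutrophils. Cells with any rose in both (2.38% to 19.6% and 4.97% to 15.9%). Doublets are argued against, as removal took -0.0022 of the rise. A few granule-rich cells are a candidate explanation: the 10% of 1150 treated mature cells with most held 98.0% of these UMIs. Cells bordering the immature class may carry the rise. In the spleen mature neutrophils went from 4.91 to 16.4 of these UMIs per cell and monocytes from 2.79 to 2.19. Doublets and the spread over cells were not tested there. For Elane and Mpo free RNA remains a candidate explanation, as T, NK, dendritic and cluster 9 cells of the saline spleens held 1.61 times the UMIs of mature neutrophils (0.322 against 0.200 per cell, and 0.037 against 0.021 in treated spleens). Their falls in mature neutrophils are therefore not evidence of a change in those cells.

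Shares of single mice stood apart from the other 3 of their group in 4 of 70 groups tested, where chance gives about 1 in 20. Monocytes of mouse 15 (treated, Treatment 1) were 15.9% in blood (others 38.2% to 42.1%) and 10.9% in spleen (others 17.8% to 18.6%). Immature neutrophils of saline mouse 1 were 11.2% in marrow (others 17.2% to 17.7%), and those of saline mouse 8 with Treatment 1 were 0.113% in Organ 1 (others 0%), which is 1 cell of 883.

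Differences between groups were tested directly. The treatment effect on mature neutrophils differed between spleen and marrow in 253 genes, led by granule genes such as Ltf and Ngp, and the Treatment 1 effect differed between treated and saline mice in 89 genes in the spleen and 15 in the blood. For shares, in two-sided permutation tests, the Treatment 1 effect in treated mice minus that in saline mice was -13.3 points for mature neutrophils in marrow (p = 0.045, adjusted p = 0.292), 2.55 for erythroid cells in the spleen (p = 0.029, adjusted p = 0.133), -5.82 and -8.92 for immature neutrophils in blood and Organ 1 (p = 0.029 and 0.028, adjusted p = 0.343 and 0.243) and 21.6 for monocytes in Organ 1 (p = 0.035, adjusted p = 0.243). None passed after adjustment.

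Surface antibodies of the second experiment, which no comparison used, differed between the RNA classes. Ly6G, the antigen of granulocytes, had a mean of 183 counts in mature neutrophils (157 in immature, 8.29 in monocytes), CD115, the receptor of macrophage growth factor, 85.7 in monocytes (3.95 in mature neutrophils), and cKit 58.5 in 15 HSPC (1.19 in mature neutrophils). The HSPC had a median of 0 for cKit and counts in 40% of cells, while immature neutrophils had a mean of 7.69, a median of 3 and counts in 64.4%.

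Other splits of the same mice show how often a regrouping gives as many genes as the real one. For treated against saline mice, 1 of 34 splits (the real one) did so in each of the 12 comparisons split. This is the smallest share 34 splits allow and, unadjusted, argues against chance only for each comparison alone. Each arm had its own lanes, so the splits cannot tell treatment from lanes. Marrow proNeu cells, with 2 treated mice, were not split. The real and highest other counts were 1049 and 1 in marrow, 4304 and 1 in spleen, 186 and 2 in blood, 339 and 1 in Organ 1, 485 and 1 in marrow preNeu, 240 and 0 in marrow immature, 414 and 2 in marrow mature, 146 and 4 in spleen immature, 563 and 1 in spleen mature, 1578 and 3 in spleen monocytes, 106 and 6 in blood mature and 83 and 21 in Organ 1 mature cells. The real split also stood alone for the organ interaction in mature neutrophils (253 and 1). It did so for Treatment 1 in treated spleen (3673 and 0), blood (879 and 3), Organ 1 (340 and 6) and spleen mature neutrophils (71 and 36). In saline Organ 1 (15 and 8) it did too, but leaving out 1 mouse gave 0 to 24 genes.

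Chance cannot be excluded by the splits for Treatment 1 in treated marrow (55 genes, 2 of 34 splits as large, highest other 80), in saline marrow (1, 9 of 34, highest 5), saline spleen (3, 5 of 34, highest 3) and saline blood (0, 34 of 34, highest 191), nor for the organ interaction in immature neutrophils (0, 34 of 34, highest 0). The same holds for the interaction of Treatment 1 with treatment in marrow (0, 100 of 100 splits, highest 2549), spleen (89, 10 of 100, highest 1666), blood (15, 7 of 100, highest 1112) and Organ 1 (0, 100 of 100, highest 1412). In the highest split of each of these 4 organs the saline mice were parted by day, mice 5 to 8 of day 2 against mice 1 to 4 of day 1. Counts several times the real ones point to a structure of the samples along the day, and within day 1 alone and day 2 alone the interaction gave 2 and 1020 genes in the spleen and 184 and 0 in the blood. The 191 genes in saline blood, with mice 1, 3, 4 and 6 set against the others, likewise point to a structure of the samples.

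For spleen against marrow the 8 splits are too few: 1729 genes and a highest other of 0 in saline mature neutrophils, and 20 and 1, 79 and 0, and 105 and 2 in preNeu, immature and mature cells of treated mice.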

How the results depend on the processing

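The tests added after the results were seen are named with the alternatives. Of 669 counts of changed genes under an alternative, 382 stayed within 1.5 times the count reported and 287 did not. Of 5253 folds of named genes 4584 kept their direction and their call, 646 kept the direction and lost the call, and 23 turned. No gene list turned in 804 tests, but 415 lost their call, and of the 267 lists called 6 held with an estimated correlation and 113 with fry, which called 136 lists in all. For the counts below the cause was not tested, except where fewer mice, fewer cells or a stricter fold make them by construction.

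RLE factors left 31 of 32 counts within 1.5 times, the exception being Treatment 1 interaction spleen 33. Doublet removal moved Treatment 1 in saline mice (blood 1, Organ 1 7) and Treatment 1 interaction (blood 2). The filter on genes and mitochondria moved treated against saline (marrow proNeu 46), spleen against marrow (mature of treated mice 36) and Treatment 1 interaction (spleen 57, blood 8). At least 50 cells per sum moved treated against saline (marrow preNeu 35, with 1 treated mouse left, and spleen immature 44, with 1 saline mouse left). The second clustering moved treated against saline (spleen mature 350), spleen against marrow (preNeu of treated mice 0, mature of treated mice 170), organ interaction (mature 30) and Treatment 1 in treated mice (spleen mature 26). DESeq2 moved treated against saline (Organ 1 562, marrow proNeu 305, marrow preNeu 322, marrow mature 274), spleen against marrow (mature of saline mice 952, preNeu of treated mice 4, immature of treated mice 18, mature of treated mice 29), Treatment 1 in treated mice (blood 554, spleen mature 41), Treatment 1 in saline mice (spleen 9, blood 1) and Treatment 1 interaction (spleen 323, blood 29, Organ 1 14). Without a filter on low counts the moved counts were treated against saline (blood 417, Organ 1 1029, marrow immature 156, blood mature 160, Organ 1 mature 146), spleen against marrow (preNeu of treated mice 39), Treatment 1 in treated mice (marrow 305, Organ 1 817), Treatment 1 in saline mice (marrow 31, spleen 150, blood 53, Organ 1 23) and Treatment 1 interaction (marrow 33, spleen 495, blood 164, Organ 1 125). With equal numbers of cells per mouse they were treated against saline (marrow 537, blood 80, marrow proNeu 266, marrow preNeu 283, marrow immature 142, marrow mature 155, spleen immature 51, spleen mature 326, spleen monocytes 532, blood mature 56, Organ 1 mature 46), spleen against marrow (mature of saline mice 516, preNeu of treated mice 7, immature of treated mice 10, mature of treated mice 28), organ interaction (mature 137), Treatment 1 in treated mice (marrow 9, blood 448, Organ 1 133), Treatment 1 in saline mice (spleen 5, Organ 1 3) and Treatment 1 interaction (spleen 0, blood 0, Organ 1 3). Against a minimum fold of 1.5 they were treated against saline (marrow 19, spleen 1914, blood 41, Organ 1 156, marrow proNeu 27, marrow preNeu 12, marrow immature 9, marrow mature 17, spleen immature 6, spleen mature 123, spleen monocytes 417, blood mature 11, Organ 1 mature 21), spleen against marrow (mature of saline mice 561, preNeu of treated mice 0, immature of treated mice 2, mature of treated mice 12), organ interaction (mature 64), Treatment 1 in treated mice (marrow 1, spleen 609, blood 50, Organ 1 43, spleen mature 9), Treatment 1 in saline mice (marrow 0, Organ 1 2) and Treatment 1 interaction (spleen 0, blood 1).

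Without the mouse block the counts moved were those of spleen against marrow (preNeu of treated mice 11, mature of treated mice 64). With it, those of the organ interaction (immature 1, mature 401). Without the day term they were treated against saline (blood 96, marrow proNeu 356), Treatment 1 in treated mice (marrow 0, blood 406, Organ 1 10), Treatment 1 in saline mice (marrow 0, spleen 0, Organ 1 1) and Treatment 1 interaction (spleen 2, blood 0). Day 1 alone gave treated against saline (marrow 2215, blood 388, Organ 1 2014, marrow preNeu 740, marrow immature 363, blood mature 448, Organ 1 mature 14), spleen against marrow (mature of saline mice 704, preNeu of treated mice 8, immature of treated mice 21), organ interaction (immature 7, mature 89), Treatment 1 in treated mice (marrow 19, spleen 1269, Organ 1 19), Treatment 1 in saline mice (marrow 0, spleen 0, Organ 1 2) and Treatment 1 interaction (marrow 2, spleen 2, blood 184, Organ 1 14). Day 2 alone gave treated against saline (blood 25, marrow proNeu 325, marrow preNeu 54, marrow immature 80, marrow mature 183, spleen mature 195, spleen monocytes 257, blood mature 27), spleen against marrow (immature of treated mice 14, mature of treated mice 28), organ interaction (mature 118), Treatment 1 in treated mice (blood 50, spleen mature 8), Treatment 1 in saline mice (marrow 10, spleen 5) and Treatment 1 interaction (marrow 3, spleen 1020, blood 0, Organ 1 1). Mice with Treatment 1 alone gave treated against saline (marrow 1706, blood 19, marrow proNeu 890, marrow preNeu 1080, marrow immature 532, spleen immature 55, blood mature 47), spleen against marrow (preNeu of treated mice 10, immature of treated mice 19, mature of treated mice 706) and organ interaction (mature 36). All mice, with Treatment 1 as a term, gave treated against saline (marrow 3269, blood 312, Organ 1 1271, marrow proNeu 1643, marrow preNeu 1591, marrow immature 850, marrow mature 957, spleen immature 377, spleen mature 952, spleen monocytes 2766, blood mature 303, Organ 1 mature 232).

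Leaving out 1 mouse gave the following ranges, with the mice whose omission moved the count past 1.5 times. Treated against saline: marrow 226 to 1163 (mice 1, 5, 6, 9, 10, 13), blood 64 to 291 (mice 2, 5, 9, 14), Organ 1 138 to 481 (mice 2, 9, 14), marrow proNeu 65 to 400 (mice 2, 10, 14), marrow preNeu 201 to 483 (mice 1, 2, 9, 10), marrow immature 104 to 242 (mice 1, 2, 9, 10), marrow mature 231 to 386 (mice 1, 10), spleen immature 96 to 122 (mouse 5), spleen mature 369 to 568 (mouse 9), spleen monocytes 1015 to 1874 (mouse 2), blood mature 48 to 203 (mice 1, 5, 9, 10, 14), Organ 1 mature 37 to 117 (mice 5, 6, 13). Spleen against marrow: mature of saline mice 1150 to 1725 (mouse 5), preNeu of treated mice 1 to 20 (mice 10, 13, 14), immature of treated mice 11 to 61 (mice 9, 13, 14), mature of treated mice 27 to 148 (mice 9, 10, 13). Organ interaction: immature 0 to 1 (mouse 6), mature 158 to 240 (mice 9, 14). Treatment 1 in treated mice: marrow 12 to 212 (mice 9, 10, 12, 16), blood 403 to 1158 (mice 9, 11, 12, 16), Organ 1 95 to 746 (mice 9, 10, 11, 12, 13, 14, 16), spleen mature 39 to 133 (mice 9, 11, 13, 14, 15). Treatment 1 in saline mice: marrow 0 to 6 (mice 1, 2, 5, 7), spleen 1 to 34 (mice 2, 3, 4), blood 0 to 5 (mouse 8), Organ 1 0 to 24 (mice 2, 5, 7, 8). Treatment 1 interaction: spleen 0 to 765 (all mice but 8), blood 1 to 45 (all mice but 6, 7), Organ 1 0 to 4 (mouse 10).

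Of 334 values for shares 314 stayed. In mice with Treatment 1 the spleen shares differed by 0.513 points for HSPC, 1.62 for proNeu, 8.36 for preNeu, 15.6 for immature and -22.9 for mature neutrophils and -2.95 for T and NK cells, all without passing, and the monocyte share turned to 1.44. The second clustering turned the marrow immature share to -1.92. Within the neutrophil lineage the effects of Treatment 1 on the marrow preNeu (7.92), immature (6.47) and mature shares (-14.5) of treated mice passed (adjusted p = 0.048 in exact permutation tests). Leaving out saline mouse 2 took the call from 7 spleen shares, whose ranges were HSPC 0.786 to 1.00, proNeu 2.25 to 2.80, preNeu 13.7 to 15.2, immature 38.9 to 42.9, mature -40.8 to -33.0, monocytes -7.07 to -5.73, and T and NK cells -1.91 to -1.62. The marrow immature share ran from -0.054 to 3.1 (turned without mouse 1) and the blood mature share from -6.35 to 1.65 (turned without mouse 1 or 9).

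In mice with Treatment 1 these folds turned: Elane in marrow 0.24, Ly6g -0.41 and Cebpe -0.22 in blood, Vcam1 in marrow proNeu 0.87, Il1b in spleen mature neutrophils 0.020 and H2-Aa in spleen monocytes 0.076. In blood mature neutrophils Camp (-0.29), Ngp (-0.18), Ltf (-1.13), Wfdc17 (0.23), Cd177 (-0.006), Egr1 (0.033) and Il1b (0.27) turned. For spleen against marrow in treated mice Fcnb in preNeu (0.079) and Ltf (-0.51) and Camp (-0.99) in mature neutrophils turned. Of these folds, Vcam1 and the last 2 passed in the new direction. With all mice Vcam1 was at 0.35. The second clustering turned Ltf (0.40) and Ngp (0.19) in marrow mature neutrophils, and for spleen against marrow Ifitm3 (-0.14) and Fcnb (0.36) in preNeu and Ltf (-0.17) and Camp (-0.0014) in mature neutrophils. The cause was not tested. The difference between mice with and without Treatment 1 was not tested for the folds in blood mature neutrophils. Marrow proNeu and the preNeu comparison of organs were not run at 50 cells per sum, for want of mice, and the alternatives of the second experiment (only the 2 groups compared, leaving out each mouse) were not run, since its labels name no mouse. Where an omission, a single day or the minimum of 50 cells left 1 mouse in a group, that mouse is assumed to vary like the other group.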

Other observations

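No tests were run for this part, which gives values without explanation.

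Of 4 clusters of mature neutrophils, cluster 1 (9381 cells) was led by the cytokine Il1b, Dusp1, the interferon-induced Ifitm1 and Csf3r, and cluster 5 (3733 cells) by the granule genes Retnlg, Mmp8 and Mmp9 and the formyl peptide receptor Fpr1. Monocytes likewise held a cluster led by Ace, Nr4a1 and Cx3cr1 of patrolling monocytes (cluster 7, 2025 cells) and 1 with the histone gene Hist1h1b and the replication factor Pclaf (cluster 12, 930 cells).

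Cluster 9 (1211 cells, 17.9% doublet-like) with Ace, Cd300e and Treml4 did not meet the naming rule.

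On the surface of cells of the second experiment, MHC class II had a mean of 131 counts on 139 dendritic cells and 0.867 to 1.29 on the other classes measured. F4/80 and B220 had no counts on any cell, and CD3 had 0 counts on 46 T and NK cells.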
